A study of Mus musculus with 6 samples.

How the data were processed

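Total RNA was measured in 6 libraries of the mouse cell line D2211B, 3 treated with nutlin 3a and 3 with nutlin 3b. Nutlin 3a is the enantiomer that binds MDM2 and blocks its hold on the tumour suppressor TRP53, and nutlin 3b is the mirror-image form used as its control. Per the labels' protocols, both compounds were applied at 30 µM for 72 h, cells were grown at 39.5 °C without interferon-gamma, and stranded libraries were made from 100 ng of RNA after removal of ribosomal RNA. Per the submitters' processing notes, STAR, featureCounts and Subread were used with genome build mm10. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here.

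Each deposited table lists 43346 genes with 2 values per library, and both came from the authors. The first is a raw read count per gene, which the authors deposited without normalization. The second is RPKM, which per the file headers is given beside the count. Each deposited RPKM value equalled the count scaled by the library total and by the gene length plus 1 base, to within a relative difference of 9.34e-07. The column of nutlin 3a library 3 carries the word replacements in its name, and its meaning is not given in the sources used here. All 37 genes of the mitochondrial chromosome were listed at 0 in all 6 libraries, so the fixed list of 13 mitochondrially encoded genes had 0 tested members and was not assessed. Total counts per library ran from 43292559 to 67418782.

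Libraries were grouped by the compound in their titles. The library numbers (3, 7 and 11 for nutlin 3a; 1, 5 and 9 for nutlin 3b) are not shared between the groups, and nothing in the labels says that the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. No libraries differed by as little as counting noise: the lowest chi-square per degree of freedom was 114, between nutlin 3b libraries 5 and 9.

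The counts were tested with edgeR 4.0.16 (quasi-likelihood test, robust, TMM factors) in R 4.3.3 after filterByExpr with its default minimum count of 10. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05, and calls with an absolute log2 fold change of at least 1 were also counted. Levels are given as TMM-normalized CPM (counts scaled to the library total and its TMM factor), as mean ± SD with n = 3. Fold changes are nutlin 3a over nutlin 3b. A gene with 0 counts in every library of a group was given a bound from 3 counts per library. Confidence intervals are at 95%. Exact binomial intervals of shares cover counting error only, while intervals of fold changes also take in the spread between libraries.

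Before the data were examined, 26 gene lists were fixed, along with the tests, the alternatives and the rule for naming genes. Lists were tested with camera from limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, with camera using an estimated correlation, and with fry. The p-values were adjusted over the 25 lists with at least 3 tested members. Fry asks whether the genes of a list move on balance in a single direction, and does not compare the list with other genes. The rule named 10 fixed genes (Trp53, Mdm2, Cdkn1a, Kit, Ano1, Cd44, Cd34, Mki67, Cdkn2a, Lmnb1). It also named the 8 largest rises and 8 largest falls among changed genes with a mean of at least 5 CPM, no overlap between groups and a conventional symbol. In each list it named the 3 members with the smallest p and any member needed to describe the list's count. The members named for that last reason, such as Pmaip1, Bbc3, Brca1, Col6a3, Gapdh and Msln, were chosen after their values were seen. Of the list symbols, Tigar was found as 9630033F20Rik, Gucy1a1 as Gucy1a3, Gucy1b1 as Gucy1b3 and Adgre1 as Emr1.

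The deposited RPKM values were tested with limma (trend, robust) on log2(RPKM + 0.5), for genes at or above 0.5 RPKM in 3 or more libraries. Fold changes on that scale understate the change of low genes. Library shares were compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 against 3. Alternatives were other size factors, other filters, DESeq2 1.42.0, limma voom, edgeR without robust fitting, other RPKM settings, each library left out in turn, and the 10 genes with the most counts left out together with mitochondrial and rRNA genes. Further alternatives were chosen after the data were seen. These used protein-coding genes only, left out nutlin 3b library 1 together with nutlin 3a library 3, or added offsets for GC content and gene length. The test with offsets was also limited to protein-coding genes.

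The tests were tried on simulated counts for nutlin 3a against nutlin 3b, with 200 planted genes. Over 17200 genes edgeR recovered 9% of the 100 genes changed 2-fold and 71% of the 100 changed 4-fold, with 11 false calls, 12.1% of its calls. DESeq2 recovered 19% and 86% over 17547 genes, with 50 false calls, 32.3% of its calls. Limma voom recovered 7% and 70% over 17200 genes, with 9 false calls. Only the 200 planted genes changed, a far smaller share than was called in the data, so these rates do not carry over to the data.

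GC content came from the longest GENCODE M21 transcript of each gene. Of the gene identifiers in the files, 98.0% were in M21, and 78.9% of these had the same start and end, so coordinates are those of the files (mm10). Overlaps were looked up for 93 named genes, without the members named only to describe a list's count. Of the 92 found in M21, 39 overlapped a gene on the other strand, among them Angptl7 (within Mtor), Timp1 (within Syn1), Htra2, Tagln, Fgf2, Csf1r, Plk3, Tk1 and Irf7. Without the strand setting of the counting, their values are uncertain to the extent that the partner's reads were included. Histone and ribosomal protein genes have near-identical copies or pseudogenes, so the values of single members are uncertain too.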

Results

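The series asked how raising TRP53 with nutlin 3a alters the transcriptome of stem cells of the interstitial cell of Cajal (ICC), the pacemaker cell of the gut wall. The cells were D2211B, a line from the muscle layer of the mouse stomach that carries a temperature-sensitive SV40 large T antigen gene. Libraries from 3 samples treated with nutlin 3a were compared with 3 treated with nutlin 3b, the control enantiomer, at the same dose of 30 µM and the same time of 72 h. Total counts per library ran from 47381205 to 54835424 for nutlin 3a and from 43292559 to 67418782 for nutlin 3b. No untreated or vehicle library was among the samples analysed here.

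The libraries separated by compound. The first principal component held 63.5% of the variance and parted the groups, and Pearson correlations of log2 CPM were 0.972 to 0.973 within nutlin 3a and 0.868 to 0.905 between groups. Nutlin 3b library 1 stood apart from nutlin 3b libraries 5 and 9: its correlations with them were 0.946 and 0.944, against 0.980 between those libraries. Malat1, a nuclear long noncoding RNA, took 0.211% of the counts of library 1 (95% exact binomial interval 0.210 to 0.212%), against 3.39% in library 5 and 2.94% in library 9. Rn7sk, the RNA of the 7SK particle that holds back transcription elongation, took 2.14, 5.83 and 9.41% in nutlin 3a libraries 3, 7 and 11, and 0.792, 3.11 and 2.39% in nutlin 3b libraries 1, 5 and 9. The share of snoRNA genes was 0.914% ± 0.634 (SD, n = 3) with nutlin 3a and 0.252% ± 0.120 with nutlin 3b (exact permutation p = 0.1, the smallest possible; 0.45 adjusted over 15 quantities).

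**Figure D1:**
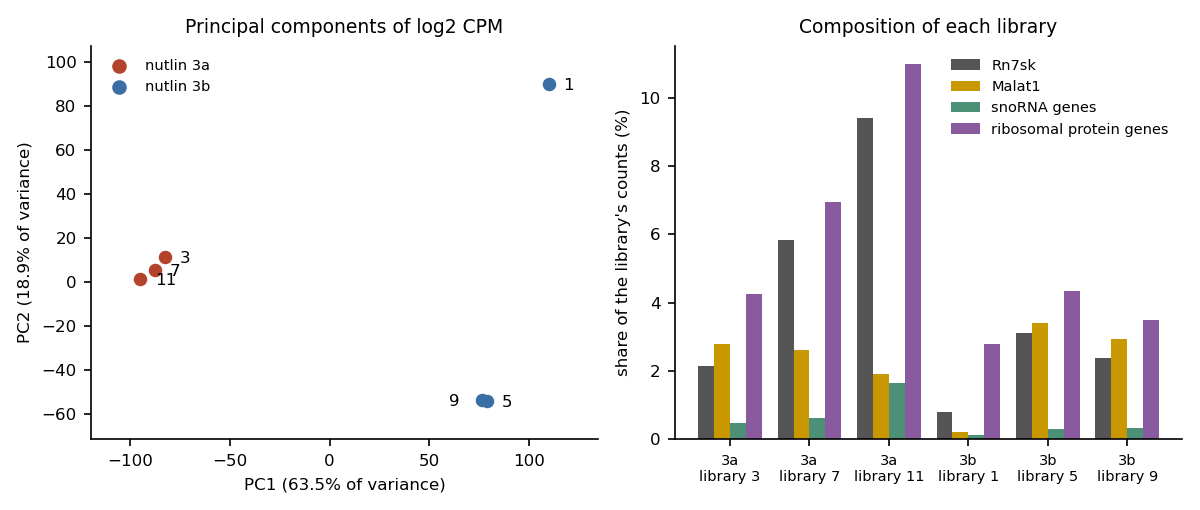
Left, the first 2 principal components of log2 CPM, with each point a library marked by its number. Right, the share of each library's counts (%) in Rn7sk, Malat1, snoRNA genes and ribosomal protein genes. Nutlin 3b library 1 lies apart from libraries 5 and 9 and has 0.211% of its counts in Malat1.

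The response of TRP53 target genes was examined first, as a check on the labels. Mdm2, the ubiquitin ligase that is both target and inhibitor of TRP53, was at 2813 ± 387 CPM (SD, n = 3) with nutlin 3a and 1151 ± 196 CPM with nutlin 3b, a 2.44-fold rise (log2 fold change 1.29, SE 0.37, edgeR adjusted p = 0.0283). Cdkn1a, the cell cycle inhibitor p21, did not differ detectably: 384 ± 21.7 against 393 ± 141 CPM, log2 fold change -0.03 with a 95% interval from -0.74 to 0.67. Trp53 itself was at 50.3 ± 14.0 against 61.3 ± 11.8 CPM (log2 fold change -0.29, interval -0.88 to 0.30). This is an RNA level, and it does not show whether TRP53 protein was raised. In the files these genes are ENSMUSG00000020184 (Mdm2, mm10 chromosome 10, 117688888 to 117710758), ENSMUSG00000023067 (Cdkn1a, chromosome 17, 29090979 to 29100722) and ENSMUSG00000059552 (Trp53, chromosome 11, 69580359 to 69591873).

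Of 41 p53 target genes, 14 rose, 2 fell and 25 did not pass the test, with a median log2 fold change of 0.56. The same 14 and 2 were counted when p was adjusted over the list alone. The death receptor gene Fas rose 3.87-fold (311 ± 24.8 against 80.5 ± 3.87 CPM, edgeR adjusted p = 0.000558) and Zfp365 2.92-fold. The BH3-only gene Pmaip1 (Noxa) rose by a log2 fold change of 2.47, the secreted factor gene Gdf15 by 2.12 and the phosphatase gene Ppm1d by 1.07. The 2 that fell were Plk3, a stress-responsive kinase gene (4.30-fold lower), and Bbc3, the BH3-only gene Puma (log2 fold change -1.06). The list stood above other genes by camera (adjusted p = 5.30e-05; adjusted p = 0.342 with an estimated correlation). Fry called the list higher (adjusted p = 0.0119), but not without nutlin 3a library 11 (fry adjusted p = 0.0797). The number of rises was 8 without nutlin 3a library 7 or 11 or nutlin 3b library 5, and 9 without nutlin 3b library 9. It was 19 without nutlin 3b library 1. The Mdm2 call was lost on leaving out any library except nutlin 3b library 1 (edgeR adjusted p 0.0511 to 0.120). The log2 fold change of Mdm2 stayed between 1.22 and 1.54 in all 22 alternatives. Bbc3 lost its call in 12 of 22 alternatives. Among them were those without nutlin 3a library 3 or 11 or nutlin 3b library 5 or 9, which left 1 fall in the list. Gdf15 was not called without nutlin 3a library 7 or 11 (edgeR adjusted p = 0.0596 and 0.0569), nor Ppm1d without nutlin 3b library 5 (0.0525). The log2 fold change of Pmaip1 was 3.08 without nutlin 3b library 9, and that of Bbc3 was -0.24 with offsets for GC content and gene length (edgeR adjusted p = 0.370).

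**Figure D2:**
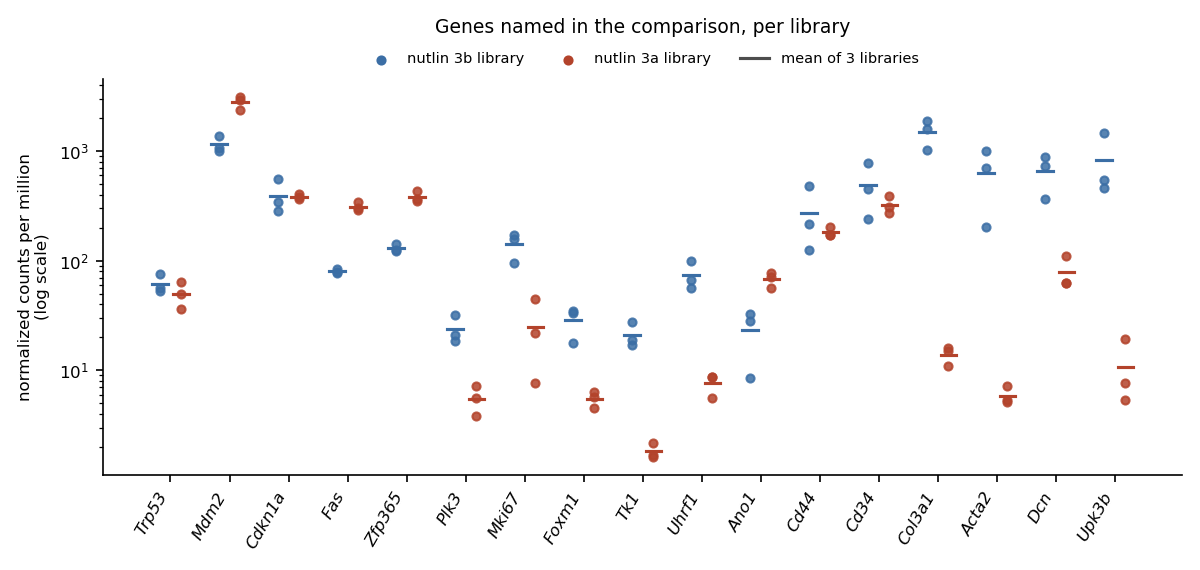
Normalized CPM (log axis) of 17 named genes in each of the 6 libraries, with points for libraries and bars for the mean of 3. Mdm2 and Fas lie higher in every nutlin 3a library than in any nutlin 3b library, Cdkn1a and Trp53 overlap between the groups, and Col3a1 falls from 1503 to 14.0 CPM.

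Across the transcriptome, 4881 of 17547 tested genes (27.8%) changed, 1875 higher and 3006 lower with nutlin 3a. Of these, 1535 rose and 2567 fell by at least 2-fold. The groups did not overlap for 8042 tested genes (45.8%, against 10% by chance). Contractile and matrix genes were among the largest falls. Angptl7, a secreted angiopoietin-like protein gene, was 381-fold lower (0.464 ± 0.0407 against 177 ± 107 CPM, edgeR adjusted p = 0.000116). The Wnt inhibitor gene Sfrp4 was 130-fold lower, the fibrillar collagen gene Col3a1 108-fold (14.0 ± 2.70 against 1503 ± 440 CPM) and the smooth muscle actin gene Acta2 107-fold (5.89 ± 1.11 against 632 ± 399 CPM). The other large falls were the myosin light chain gene Myl9 (112-fold, 0.0975 ± 0.0265 against 11.1 ± 11.0 CPM), the mesothelial gene Lrrn4 (103-fold), the laminin gene Lama4 (100-fold, 0.116 ± 0.0511 against 12.1 ± 13.6 CPM) and the neutral sphingomyelinase gene Smpd3 (87.1-fold). Myl9 was at 0.246 CPM in nutlin 3b library 1, against 22.2 and 10.7 CPM in libraries 5 and 9, so its fold rested on those 2 libraries and was 53.7 without library 5. Without nutlin 3b library 1 the falls of Lama4 and Smpd3 were 33.9-fold and 52.6-fold, and without nutlin 3a library 7 that of Sfrp4 was 223-fold. Large rises were in genes at low levels with nutlin 3b. Grm8, a glutamate receptor gene, rose 67.1-fold (10.5 ± 3.92 against 0.152 ± 0.0560 CPM). The germline Tudor-domain gene Tdrd5 rose 60.2-fold, Fam159b 59.0-fold, the muscle creatine kinase gene Ckm 57.1-fold, the phosphatase gene Ptprt 45.8-fold, Ttll10 40.7-fold, the calcium channel gene Cacna1e 40.4-fold (159 ± 33.0 against 3.93 ± 0.859 CPM) and the glucose transporter gene Slc5a1 34.6-fold. Without nutlin 3b library 1 the rises of Tdrd5, Ptprt and Slc5a1 were 127-fold, 115-fold and 97.0-fold, above the other 5, so the order of these 8 rises depended on that library. The edgeR adjusted p of the 8 rises ran from 9.33e-05 (Cacna1e) to 0.000974 (Slc5a1). The number of changed genes was 3043 without nutlin 3a library 11, with 1754 lower, and 1243 were higher without nutlin 3a library 7. Leaving out nutlin 3a library 3 and nutlin 3b library 1 together gave 4852, of which 3831 were among the 4881, all in the same direction. Myl9 was not called by limma voom or without a filter, and the unfiltered RPKM test called neither Myl9 nor Lama4.

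Proliferation genes that passed the test were mostly lower with nutlin 3a. Mki67, a marker of cycling cells, was 5.72-fold lower (24.7 ± 18.6 against 141 ± 40.7 CPM, edgeR adjusted p = 0.00880). Of 49 genes of G1/S and DNA replication, 25 fell and 1 (Orc1) rose; adjusted over the list alone these were 28 and 3. Thymidine kinase gene Tk1 was 11.5-fold lower, cyclin E1 gene Ccne1 12.2-fold and Uhrf1, needed to maintain DNA methylation, 9.59-fold (7.69 ± 1.83 against 73.8 ± 22.1 CPM). Of 59 G2/M and mitosis genes, 36 fell and 2 (Ncapd2, Spc25) rose; adjusted over the list alone, 43 fell and 2 rose. The mitotic kinesin gene Kif20a was 10.5-fold lower, the mitotic kinase gene Plk1 8.28-fold and the transcription factor gene Foxm1 5.17-fold. Of 66 replication-dependent histone genes, 33 fell and none rose (43 fell adjusted over the list alone), with a median log2 fold change of -1.63. Hist1h2bh was 15.5-fold and Hist1h2bn 6.30-fold lower, and Hist1h2af was at 0.0471 ± 0.00551 against 0.866 ± 0.155 CPM. Camera placed these 3 lists below other genes (adjusted p = 0.000338 for G1/S, 6.87e-09 for G2/M and 6.80e-11 for histones). With an estimated correlation the adjusted p was 0.352 for G1/S, 0.541 for G2/M and 0.415 for histones, and fry did not call the G2/M list (adjusted p = 0.0557). Cdkn2a, the gene of p16 and p19ARF, was 6.32-fold lower (9.92 ± 3.64 against 62.7 ± 7.93 CPM) and the nuclear lamin gene Lmnb1 5.11-fold lower (10.9 ± 1.79 against 55.7 ± 12.9 CPM). Fewer members fell when libraries were left out: 13 of the G1/S list without nutlin 3a library 11 and 16 without library 7, and 20, 20 and 19 histone genes without nutlin 3a library 3, nutlin 3a library 11 and nutlin 3b library 5. Rises numbered 4 in each of the G1/S and G2/M lists without nutlin 3b library 1. They numbered 0 in the G1/S list without nutlin 3a library 3 or 7 or nutlin 3b library 9, and in the G2/M list 0 without nutlin 3a library 11 or nutlin 3b library 5 or 9 and 1 without nutlin 3a library 3 or 7. Without nutlin 3a library 3 the fall of Mki67 was 9.55-fold, and without nutlin 3a library 7 that of Hist1h2bh was 28.2-fold. The Mki67 call was lost without a filter on low counts (edgeR adjusted p = 0.0736), and the rises of Orc1, Ncapd2 and Spc25 were each lost in 5 or more of 22 alternatives, including some that left out a single library of either group.

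Of 30 genes of homologous recombination and the Fanconi anaemia pathway, 8 fell and 3 rose (10 and 3 adjusted over the list alone), and the list did not stand apart from other genes (camera adjusted p = 0.271). The helicase gene Helq rose 4.54-fold and Fancc 4.43-fold, with Mus81 the remaining rise, while the repair genes Brip1 and Brca1 were 2.67-fold and 3.20-fold lower. Recombination genes that fell numbered 3, 4 and 0 without nutlin 3a libraries 3, 7 and 11, and 5 and 2 without nutlin 3b libraries 1 and 5. The Brca1 call was lost without nutlin 3a library 7 or 11 (edgeR adjusted p = 0.0543 and 0.0609).

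Most genes of the extracellular matrix list fell. Of 33 tested collagen and matrix genes, 27 fell and 1 rose (27 and 2 adjusted over the list alone), with a median log2 fold change of -3.22. Besides Col3a1, Col6a2 was 52.9-fold lower (0.973 ± 0.411 against 51.9 ± 23.7 CPM), the elastic fibre gene Fbln5 18.9-fold lower, and the collagen I genes Col1a1 and Col1a2 had log2 fold changes of -4.82 and -5.74. The single rise was Col6a3 (2.23 ± 1.33 against 0.197 ± 0.145 CPM). Camera gave an adjusted p = 6.00e-12, and adjusted p = 0.316 with an estimated correlation. Secreted factors often linked to senescence were also lower: 17 of 33 fell and 1 (Mmp12) rose, 19 and 3 adjusted over the list alone (camera adjusted p = 0.000282; adjusted p = 0.279 with an estimated correlation). The chemokine gene Ccl2 was 28.5-fold, the protease inhibitor gene Timp1 10.7-fold and Fgf2 5.59-fold lower, and Serpine1 had a log2 fold change of -3.52. Without nutlin 3b library 9 the fall of Ccl2 was 18.8-fold and the log2 fold change of Col1a2 -4.89. The rise of Mmp12 was not called without nutlin 3a library 11 (edgeR adjusted p = 0.0839). Rises in the list of secreted factors numbered 5, 2 and 3 without nutlin 3b libraries 1, 5 and 9, and those in the matrix list 2 without nutlin 3b library 1 or 9.

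Interferon-stimulated genes were lower in 26 of 36 cases and higher in 1, Psmb9 (28 and 1 adjusted over the list alone), with a median log2 fold change of -1.83. The ubiquitin-like gene Isg15 was 16.8-fold lower (6.49 ± 2.37 against 109 ± 52.8 CPM), Oasl1 18.2-fold and the transcription factor gene Irf7 6.54-fold. Camera gave an adjusted p = 2.73e-09, and adjusted p = 0.330 with an estimated correlation.

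Glycolysis, cholesterol synthesis and stress genes that passed the test were mostly lower. Of 20 glycolysis genes, 15 fell and none rose (17 fell adjusted over the list alone): Eno1 was 5.57-fold, Pfkp 4.41-fold and Aldoc 12.8-fold lower, and Gapdh went from 278 ± 42.0 CPM with nutlin 3b to 53.3 ± 18.2 CPM with nutlin 3a. Of 23 tested members of the cholesterol synthesis list, 11 fell and none rose (13 fell adjusted over the list alone). The falls were led by Dhcr24 (9.86-fold lower), Stard4 (5.40-fold) and Fdps (4.64-fold). Of 29 genes of the integrated stress and unfolded protein responses, 15 fell and 2 (Ddit3, Dnajb9) rose (17 and 3 adjusted over the list alone). The serine synthesis genes Psat1 and Phgdh were 16.1-fold and 4.92-fold lower, and Chac1 7.28-fold. Camera adjusted p was 1.42e-07 for glycolysis, 1.30e-05 for cholesterol synthesis and 0.00119 for the stress list. With an estimated correlation the adjusted p was 0.279, 0.279 and 0.585, and fry did not call the stress list (adjusted p = 0.0722). Fewer cholesterol genes (7) fell without nutlin 3a library 11. The stress genes lower were 7 without nutlin 3a library 3, 7 without library 7 and 5 without library 11, and 7 without nutlin 3a library 3 and nutlin 3b library 1 together. Stress genes higher were 4 without nutlin 3b library 1, 0 without nutlin 3a library 11 and 1 without any other library. The fall of Psat1 was 9.12-fold without nutlin 3b library 1. The rise of Ddit3 was not called without nutlin 3a library 7 or 11 or nutlin 3b library 5 (edgeR adjusted p 0.0638 to 0.103), nor that of Dnajb9 without nutlin 3a library 3 or 11 or nutlin 3b library 9 (0.0973 to 0.103).

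Of 82 ribosomal protein genes, 20 rose and none fell (18 rose adjusted over the list alone), with a median log2 fold change of 1.04 and camera adjusted p = 9.67e-09 (adjusted p = 0.585 with an estimated correlation), and fry did not call the list (adjusted p = 0.171). Rpl9 rose 4.97-fold (4166 ± 2779 against 838 ± 205 CPM), Rps27 4.74-fold and Rpl35a 4.18-fold. These genes took 4.25, 6.94 and 11.0% of the counts of nutlin 3a libraries 3, 7 and 11, and 2.80, 4.33 and 3.48% of those of nutlin 3b libraries 1, 5 and 9. The share of Rn7sk was likewise highest in library 11. Without library 11 the rises of Rpl9 and Rpl35a were 3.23-fold and 2.73-fold. The number of rises was 3 without library 11, 11 without nutlin 3a library 7, 8 and 7 without nutlin 3b libraries 5 and 9, 48 without nutlin 3a library 3, and 52 without nutlin 3a library 3 and nutlin 3b library 1 together.

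**Figure D3:**
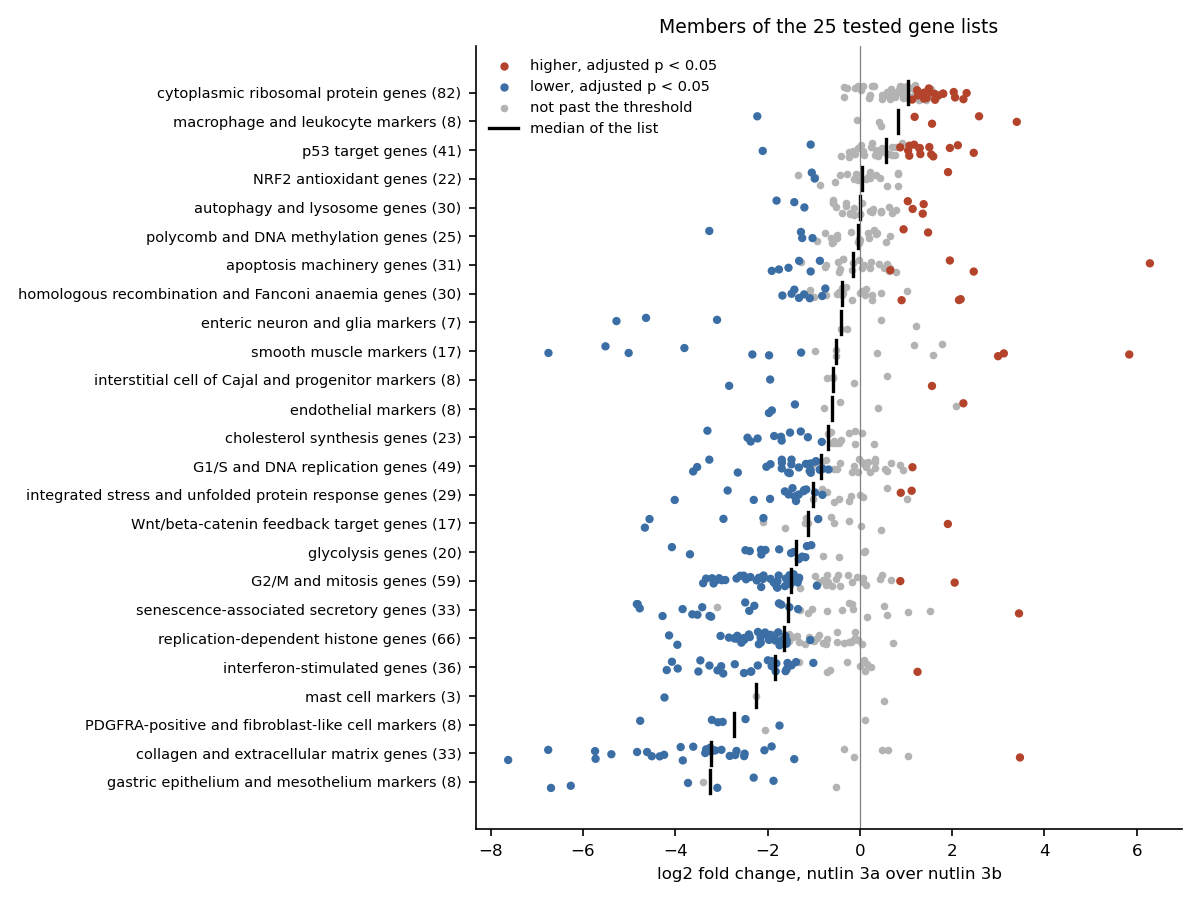
Log2 fold change (nutlin 3a over nutlin 3b) of every tested member of 25 gene lists, with the number tested in parentheses, colour for genes past the edgeR threshold and a black bar for the list median. Members with 0 counts in all nutlin 3a libraries are drawn at their bound. Medians run from -3.24 for epithelial and mesothelial markers to 1.04 for ribosomal protein genes.

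Several lists held members that moved both ways and did not stand apart from other genes by camera. Of 31 apoptosis genes, 4 rose and 6 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.849). Besides Fas, Pmaip1 and Bcl2l11, the BH3-only gene Hrk rose and was at 2.90 ± 1.84 against 0.0318 ± 0.0401 CPM, while the mitochondrial protease gene Htra2 was 3.75-fold and the survival gene Bcl2 2.92-fold lower. The other falls were Bak1, Bmf, Casp8 and Bbc3. The median of the apoptosis list was -0.15 and its mean 0.06. Of 30 autophagy and lysosome genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.564), with Atg2b up 2.61-fold, Atg5 up 2.06-fold and Tfeb 3.49-fold lower. The other autophagy rises were Ulk1 and Atg4a, and the other falls Ctsl and Map1lc3a. The median of this list was -0.0025 while camera gave its direction as up. Of 25 polycomb and DNA methylation genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.671). The polycomb gene Eed rose 2.79-fold, and the DNA methyltransferase gene Dnmt1 was 2.38-fold lower. Rnf2 also rose, and Uhrf1, Cbx4 and Cbx8 also fell. Of 22 NRF2 antioxidant genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.849). Gclc, for glutathione synthesis, rose 3.76-fold, and Me1 and Sod2 were 2.06-fold and 1.97-fold lower. The median of the NRF2 list was 0.04 and its mean -0.01. Of 17 Wnt feedback and target genes, 1 (Notum) rose and 5 fell (1 and 6 adjusted over the list alone), including Sfrp2 (25.2-fold lower), Wisp1 (7.75-fold) and Apcdd1 (4.25-fold), with Dkk2 and Znrf3. The camera adjusted p of the Wnt list was 0.0815, 0.0112 without nutlin 3b library 1 and 0.0363 without library 5, with adjusted p = 0.386 and 0.321 for these with an estimated correlation. Members that fell numbered 3 in the Wnt list without nutlin 3a library 3 or 7 or nutlin 3b library 5, 3 in the apoptosis list without nutlin 3a library 11 or nutlin 3b library 9, 1 in the autophagy list without nutlin 3a library 3 or 7 or nutlin 3b library 9, and 1 in the polycomb list without nutlin 3a library 11. In the NRF2 list 3 rose and 0 fell without nutlin 3b library 1, 0 fell without nutlin 3a library 7, and 1 fell without nutlin 3a library 3 or nutlin 3b library 5 or 9. In the Wnt list 0 rose without nutlin 3a library 7. Over all alternatives, the apoptosis list had 2 to 9 rises and 3 to 7 falls, and the NRF2 list 1 to 6 rises and 0 to 4 falls. The calls of Me1, Sod2, Dnmt1 and Brip1 were each lost without nutlin 3a library 11 (edgeR adjusted p 0.0657 to 0.0870), that of Me1 also without any other library except nutlin 3b library 9, and that of Sod2 also without nutlin 3a library 7 or nutlin 3b library 1 or 9. Bcl2l11, Bmf, Bbc3, Casp8, Mus81, Cbx4, Cbx8, Znrf3, Dkk2, Notum, Ctsl and Map1lc3a each lost their call in 2 or more alternatives, at least 1 of which left out a single library.

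Of the 8 tested ICC and progenitor markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.564). Ano1, the calcium-activated chloride channel of ICC, rose 2.95-fold (68.3 ± 11.1 against 23.1 ± 12.9 CPM, edgeR adjusted p = 0.0252). The insulin-like growth factor receptor gene Igf1r was 3.84-fold lower and the guanylate cyclase gene Gucy1a3 7.11-fold lower. Kit, the receptor that defines mature ICC, had 3, 1 and 0 counts in nutlin 3a libraries 3, 7 and 11 and 3, 1 and 0 counts in nutlin 3b libraries 1, 5 and 9. A difference in Kit was therefore not detectable at this depth. The progenitor marker Cd44 was at 183 ± 18.8 against 273 ± 184 CPM (log2 fold change -0.58, 95% interval -1.55 to 0.39). Cd34 was at 323 ± 57.7 against 487 ± 268 CPM (log2 fold change -0.59, interval -1.51 to 0.33). The Ano1 call was lost without nutlin 3a library 3 or 7 (edgeR adjusted p = 0.0737 and 0.0760), and that of Gucy1a3 was lost without any 1 of the nutlin 3a libraries. Without nutlin 3b library 1 the fall of Gucy1a3 was 2.72-fold.

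Markers of other cell types were examined for a shift in cell identity or mix. Epithelial and mesothelial markers fell in 6 of 8 cases and none rose (7 fell adjusted over the list alone; camera adjusted p = 2.16e-05; adjusted p = 0.279 with an estimated correlation). The uroplakin gene Upk3b was 76.7-fold lower (10.7 ± 7.43 against 824 ± 559 CPM), the mesothelin gene Msln went from 378 ± 151 to 44.5 ± 16.8 CPM, and the keratin gene Krt18 was 4.92-fold lower. Of 8 PDGFRA-positive and fibroblast-like cell markers, 6 fell and none rose (7 fell adjusted over the list alone; camera adjusted p = 0.00205; adjusted p = 0.279 with an estimated correlation). Decorin gene Dcn was 8.42-fold (78.8 ± 27.9 against 663 ± 268 CPM), Pdgfra 7.84-fold and Pdgfrb 9.22-fold lower. Of 17 smooth muscle markers, 7 fell and 3 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.467). Tagln was 32.2-fold lower, while Ckm, best known from striated muscle, rose with Synpo2 and Pgm5. Without nutlin 3b library 9 the falls of Pdgfra and Pdgfrb were 4.48-fold and 5.06-fold, and that of Upk3b was 44.1-fold without nutlin 3b library 1 and 126-fold without nutlin 3a library 7. Smooth muscle rises numbered 5 without nutlin 3b library 1. The Pgm5 call was lost without any 1 of the nutlin 3a libraries or without nutlin 3b library 5 (edgeR adjusted p 0.0648 to 0.133).

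Of 8 macrophage and leukocyte markers, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0678). Laptm5 rose 10.6-fold and the CSF1 receptor gene Csf1r 5.99-fold, both at low levels (2.44 ± 0.978 and 1.17 ± 0.288 CPM with nutlin 3a), and Cd14 rose 2.28-fold. Cd68 also rose, and the lysozyme gene Lyz2 fell. Of 8 endothelial markers, 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.809): Pecam1 rose 4.73-fold, and Egfl7 and Flt1 were 3.75-fold and 3.92-fold lower, with Kdr the remaining fall. Of 7 enteric neuron and glia markers, 3 fell and none rose (3 fell adjusted over the list alone; camera adjusted p = 0.157), with the intermediate filament gene Prph 38.6-fold, Uchl1 24.8-fold and the transcription factor gene Hand2 8.53-fold lower. Of 3 tested mast cell markers, 1 fell (2 adjusted over the list alone; camera adjusted p = 0.298): Ms4a2 had 0 counts in all nutlin 3a libraries and was at least 18.9-fold lower (floor of 3 counts per library). Hdc was at 0.148 ± 0.0971 against 0.702 ± 0.607 CPM and Cma1 at 1.92 ± 0.758 against 1.32 ± 1.46 CPM, neither past the threshold. Hdc was called lower by DESeq2 (adjusted p = 0.0477) and without nutlin 3b library 9 (log2 fold change -2.71, edgeR adjusted p = 0.0402), which made 2 mast cell falls. Without nutlin 3b library 1 the fall of Flt1 was 2.05-fold and not called (edgeR adjusted p = 0.0661), that of Uchl1 5.26-fold and the rise of Pecam1 7.33-fold, and without nutlin 3a library 7 the fall of Prph was 58.3-fold. Macrophage rises numbered 2 without nutlin 3a library 7 or 11, and macrophage falls 0 without nutlin 3a library 3 or 7. Endothelial falls numbered 1 without any 1 of the nutlin 3a libraries or without nutlin 3b library 9. Endothelial rises numbered 3 without nutlin 3b library 1 and 0 without nutlin 3a library 3 or 7 or nutlin 3b library 5 or 9, and the calls of Flt1, Egfl7, Kdr, Pecam1, Cd14, Cd68, Lyz2 and Uchl1 were each lost in 3 or more alternatives.

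On the deposited RPKM scale, limma called 4008 of 15473 genes, 1434 higher and 2574 lower. Of the 4008, 3655 were among the genes called from counts, all in the same direction. The number called was 2588 and 2305 without nutlin 3a libraries 7 and 11, and 2572 without nutlin 3b library 9.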

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

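Alternatives limited to protein-coding genes, with offsets for GC content and gene length, or without nutlin 3b library 1 and nutlin 3a library 3 together were chosen after the data were seen. No paired analysis was run, because the groups share no library number and the labels name no pairs. A pairing by the order of the library numbers would be a guess and was not tested. The spread between 3 libraries per group was a limit, but its size in the data was not measured. In simulated data edgeR recovered 9% of genes changed 2-fold. A far smaller share of genes changed there than was called in the data, so that rate does not carry over to the data. Of 4282 recomputed values, 3778 kept their direction and side of the threshold or stayed within 1.5 times, and 84 of 140 named genes did so in every alternative run for them. Leaving out a library gave 3043 to 5421 changed genes, against 4881, with 1243 to 2455 higher and 1754 to 2966 lower. It gave 8 to 19 p53 target genes higher, against 14, and 2305 to 3736 genes in the RPKM test, against 4008. On leaving out a library, the lowest total and the lowest count of falls came without nutlin 3a library 11. The lowest count of rises came without nutlin 3a library 7, and the highest of all 3 without nutlin 3b library 1. Fewer samples weaken the test, but the total did not drop in every case. The cause of the lower and higher counts was not tested. Without a filter the RPKM test called 3039 genes, 1019 of them higher, 2515 at least 2-fold and 7 p53 targets higher, and with a pseudocount of 1 it called 2719 at least 2-fold, since a larger pseudocount shrinks folds. With an estimated correlation 0 of the 2 higher and 0 of the 9 lower gene lists were called, and 0 of 2 lower lists of other cell types. The preset correlation is what these calls rest on. Fry, which asks a different question, called 14 lists lower and 2 higher. Of these, 5 lower and 1 higher were lists of other cell types. Some of its calls were not made by camera. These were ICC (fry adjusted p = 0.0195), Wnt (0.0218), smooth muscle (0.0215), enteric (0.0208) and mast cell genes (0.0449) lower, and macrophage markers (0.0107) higher. DESeq2 called 5712 genes and limma voom 4752. The excess of falls shrank from 1875 higher and 3006 lower to 2223 and 2583 with upper-quartile scaling, 2030 and 2450 with protein-coding genes only, and 2378 and 2558 with offsets. Upper-quartile scaling moved the median log2 fold change of all tested genes from -0.04 to 0.07. Values that turned sign had not passed the threshold before or after, and the cause was not tested. The log2 fold change of Trp53 was 0.029 with offsets. That of Cdkn1a was 0.028 with RLE factors, 0.087 with upper quartile, 0.00037 with a filter of 1 CPM, 0.015 with DESeq2, 0.036 with limma voom, 0.018 without the 10 largest genes, 0.12 with protein-coding genes only, 0.38 without both libraries and 0.30 with offsets, and -0.20 to 0.38 on leaving out a library. On leaving out a library Cd44 ran from -0.89 to 0.21, Cd34 from -0.87 to 0.015 and Cma1 from -0.0050 to 1.996, and Cd44 was at 0.10 without both libraries.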

Other observations

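The counts by symbol family and by gene class, the test of marker genes, the test for a swapped label and both tests for a loss of nuclear RNA were chosen after the results were seen.

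Of 315 tested snoRNA genes 47 rose and none fell (median log2 fold change 0.87), and of 117 snRNA genes 25 rose and none fell (median 1.28), where 1875 of all 17547 tested genes rose. The snoRNA share of the counts was 1.64% in nutlin 3a library 11 against 0.473 and 0.628% in libraries 3 and 7, and 0.115% in nutlin 3b library 1 against 0.306 and 0.335% in libraries 5 and 9. Camera adjusted p over 9 gene classes was 5.79e-10 for snoRNA and 1.16e-08 for snRNA genes (adjusted p = 0.537 for each with an estimated correlation), and fry called neither class (adjusted p = 0.240 and 0.141). Among 161 families of protein-coding genes that share a symbol stem, histone genes (33 of 65 lower, Fisher's exact adjusted p = 2.40e-05) and collagen genes (19 of 37 lower, 6 higher, exact adjusted p = 0.00577) fell more often than the 20.8% of all tested protein-coding genes that fell. Fisher's test takes the genes of a family as independent, and the fixed histone and matrix lists, of estimated correlation 0.546 and 0.360, were not called by camera at these correlations (adjusted p = 0.415 and 0.316). The matrix protease genes of the Adamts family (9 of 14 lower, exact adjusted p = 0.0544) and the interleukin and receptor genes with the stem Il (15 of 32 lower, exact adjusted p = 0.0670) did not pass with p adjusted over rises and falls of all families together, and passed with adjustment over falls alone (exact adjusted p = 0.0272 and 0.0335).

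Several p53 target genes already ranked high by CPM with nutlin 3b, a scale that is not corrected for gene length. Ccng1 was at 2629 CPM (rank 11 of 17547 tested genes), Mdm2 at 1151 CPM (rank 41), Trp53inp1 at 1050 CPM (rank 50) and Cdkn1a at 393 CPM (rank 314). Other targets ranked low, such as Pmaip1 (rank 10098) and Gdf15 (rank 13194). No untreated library was analysed here to set these levels against.

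Collagen and matrix genes were lower with nutlin 3a, with a median log2 fold change of -3.22. Uneven small RNA shares do not account for it, since the median was -3.07 with protein-coding genes alone, nor does GC content and length bias, since it was -2.75 with offsets. Fewer mesothelial or fibroblast-like cells among those harvested may also contribute and cannot be told apart from a change within cells. The 14 markers of these cells at 5 CPM or more with nutlin 3b all had negative log2 fold changes, from -6.69 to -0.52 with an SD of 1.65, but cells of both types also make matrix. The 5 CPM filter looked only at nutlin 3b, so a marker low there and higher with nutlin 3a could not enter. Krt19, Fbln1 and Krt8 did not pass the threshold (edgeR adjusted p = 0.481, 0.074 and 0.0597). A response to nutlin 3a within the cells stays open as well.

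Ribosomal protein genes had a median log2 fold change of 1.04, with 20 of 82 past the threshold. With protein-coding genes only the median was 1.19, with 36 of 80 past the threshold. Adding GC content and length offsets to that set gave a median of 1.07, with 45 of 80 past it. Without library 11, which had the highest shares of Rn7sk and ribosomal protein counts, the median was 0.63 (quartiles 0.32 and 0.89). A bound of 0.5 set before this value was seen would have excluded that library as the cause. The value passed it by less than the spread of the genes, and a stricter rule was set after it was seen. It asked for a lower quartile of 0.5 and for libraries 3 and 7 both above every nutlin 3b library, and neither part was met. The list's median log2 CPM was 8.46 and 9.39 in nutlin 3a libraries 3 and 7, against 8.27, 8.84 and 8.48 in nutlin 3b libraries 1, 5 and 9. The part of library 11 may therefore be large and is left open.

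Nutlin 3b library 1 stood apart from nutlin 3b libraries 5 and 9. Malat1 was 13.7-fold, the imprinted noncoding RNA H19 68.1-fold and Col8a1 72.9-fold lower in it than in their mean. A swapped label is argued against by its correlations, which were higher with libraries 5 and 9 than with nutlin 3a by 0.0702, and depth by a correlation of 0.946 with library 5 after thinning, against 0.980 between libraries 5 and 9. A loss of nuclear RNA may contribute and is left open, since where in the cell these mRNAs lie was not tested: of its protein-coding genes 61 were 8-fold or more lower and 10 higher, against 8 that differed either way between libraries 5 and 9. It is open too for snoRNA and snRNA genes (medians -1.50 and -0.77), because the cytoplasmic Rny1, Rny3 and Vaultrc5 were also lower, by a mean log2 difference of -0.88.

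Of the 10 splits of the 6 libraries into 3 and 3, the real split was the only 1 with as many changed genes (4881 by edgeR, against at most 0 in the other splits, where 61 to 526 genes had an unadjusted p below 0.05). Each of the other splits put libraries of both compounds in the same group. The difference between compounds then added to the spread within groups, so few calls could be made there. So few splits also cannot give a share under 0.05, and no conclusion is drawn from this comparison.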
